A study of Mus musculus with 182 samples.

How the data were processed

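Single germinal centre B cells from the spleen of C57BL/6 mice were measured by RNA sequencing, with 1 library for each of 182 cells. The mice had been given 100 μg NP(23)-KLH, a hapten coupled to a carrier protein, with 50% alum and 1 μg LPS, and spleens were taken on day 13. T cells, CD11c+ cells and IgD+ B cells were depleted with antibodies on magnetic columns before sorting. The sample labels give the sorted phenotype as B220+, Fas high, GL7 high and NP-binding, while the design text of the series gives a gate on B220, Fas and GL7 and lists NP only among the stains. Cells were captured on the Fluidigm C1 system, on which their separation was scored by eye, and cDNA and libraries were made with SMARTer and Nextera XT chemistry.

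The deposited table holds a normalized signal per gene and cell that is not on a log scale. The submitters' processing notes name TopHat2 2.0, Cufflinks 2.2, Cuffdiff without a version, and the mm10 build. The starting unit, gene annotation, gene filter and normalization are not given in the sources used here. The values were not whole numbers and their sums differed between cells, so they were treated neither as counts nor as TPM, and no model for counts was used. The table had 17035 rows for 17034 gene symbols. The symbol on 2 rows was kept from 1 row, and 20 symbols had been turned into dates by a spreadsheet and could not be matched to lists. The sequencing depth of each cell was unknown, because no read counts were used here.

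The structure of the values was checked before the comparisons. Cells shared a ladder of values by rank, as quantile normalization gives, and this ladder was shifted gene by gene in a way that split the columns into 2 sets. Set 1 held cells 1 to 96 (96 cells) and set 2 held cells 97 to 182 (86 cells). Between cells of different sets, 0% of genes had an exactly equal non-zero value, while any 2 cells of the same set had equal values, floors included, at 61.9% of genes or more. Each gene also had its own lowest value in each set, called its floor here, at which its undetected cells stood. The floor was 0 for 40.0% of genes in set 1 and 14.1% in set 2, and it reached 1 or more for 11 and 32 genes, which therefore count as detected in every cell of that set. The sets were treated as technical batches found from the values, though whether they match capture runs or animals is unknown. Each relation called over all cells is given within both sets, as is any other whose percentile passed the threshold within a set.

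The lists of genes, the comparisons, the thresholds and most alternatives were fixed before the data were examined. There were 27 lists, which covered the zones and cell types of the germinal centre, other cell types of the spleen, the cell cycle, metabolism, stress, signalling, cell death and antibody genes. A gene was called detected in a cell at a value of at least 1. Shares of cells are given with exact Clopper-Pearson 95% intervals, which cover counting error over cells only.

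A list score was the mean over members of the z-score of log2(value + 1), using members detected in at least 10% of cells, and a list with fewer than 3 such members got no score. For a pair of scores, Spearman's rho and Pearson's r were taken across cells, with members shared by both lists left out. The rho was placed as a percentile among 10000 random pairs of lists of the same sizes, drawn from the 50 genes nearest each member in mean level. A value was called when its percentile lay below 2.5 or above 97.5. The same rule served for the coherence of a list, which is the mean rho over pairs of its members, and for 19 gene pairs. Pearson's r was repeated without the 2 cells farthest from the median of the first score. No p-value was computed, since the cells were treated as 1 biological sample and not as replicates, and no second group exists.

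The dominant heavy chain gene of a cell was the constant gene with over 50% of the summed values of the heavy chain constant genes, where this sum was at least 10. The same rule was applied to heavy chain variable genes after the data had been seen. Principal components used the 1000 genes with the largest variance over a lowess trend (fraction 0.3) on the mean, out of 5409 genes detected in at least 10% of cells and without immunoglobulin genes. Ward clustering on 10 components was run for 2 to 6 clusters, and the number with the highest mean silhouette was taken. No doublet caller was run. Every detected gene outside the zone and other lists, 5161 genes in all, was correlated with the light zone score minus the dark zone score.

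Genes were named by a rule. All members of the lists for germinal centre B cells, dark zone, light zone, heavy and light chain constant genes and NP-binding variable genes could be named. Of each other list, up to 4 members closest to the mean of the rest could be named, or for other cell types up to 3 found in most cells. The rule added the 10 highest and 10 lowest genes along the zone axis, the members of the gene pairs, the 10 genes with the largest variance over the trend and the 5 with the highest mean. Leading genes of clusters and of principal components are named to describe them, and any other gene is said to have been chosen after its values were seen.

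Alternatives fixed at the start were pseudocounts of 0.1 and 10, no filter on list members, rescaling to equal sums without immunoglobulin genes, and a term for the number of detected genes. Others were detection above 0 or at 5, stricter rules for isotypes (80% or a sum of 100), 500 or 2000 variable genes, genes in at least 30% of cells, clustering without cell cycle genes, k-means, and leaving out cells over 3 median absolute deviations (MAD) from the median number of detected genes. That median was 1886.5 with a MAD of 42.5, and the filter removed 86 cells, all 86 of set 2, so it amounts to set 1 alone. Further alternatives were chosen after seeing the data. These were set 2 alone, scores made within sets, detection above the floor, a term for genes above the floor and set, each cluster alone, 3 clusters, clustering without members of any list, and a filter of 3 MAD on genes above the floor (median 2404 with a MAD of 365.5), which removed 18 cells. Each alternative used 2000 random lists.

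The scoring was tested on simulated data, made by shuffling each gene's values among the cells of a set, in 20 datasets. With nothing planted, the pair of zone scores was called in 1 of 20, and with an opposite shift of 0.25 SD planted in the lists it was called in 20 of 20. A planted group of 24 cells with 200 genes shifted by 2 SD was recovered with a median silhouette of 0.340, against 0.0531 with none planted, while a shift of 1 SD gave 0.0618 and was mostly missed. Shuffling removes relations between genes, including those from depth and the cell cycle. With none planted the first component held 1.10% of the variance, against 5.74% in the real data. The simulated values are therefore no reference for the calls or silhouettes of the real cells.

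Gene positions are those of GENCODE vM21 on mm10, matched by symbol. The work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9. The planned share of lambda light chains was left out, because no light chain constant or lambda variable gene is in the table.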

Results

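The data were transcriptomes of 182 single germinal centre B cells, the activated B cells that divide, mutate their antibody genes and are selected in the spleen after immunisation. All 182 cells formed 1 group from day 13 after immunisation with NP(23)-KLH in alum and LPS. The labels name no animal, so the number of mice is unknown and the group was treated as 1 biological sample. No replicates could be told apart, there was no group to compare with, and the comparisons run across cells. Intervals cover counting error only. A median of 1904 genes (range 1873 to 1946) were detected per cell in set 1 of the columns and 1690 (995 to 1741) in set 2. The narrow range in set 1 goes with a ladder of values that cells share by rank. The number of genes above their floor had a median of 2666.5 (1904 to 4498) in set 1 and 2188.5 (980 to 5150) in set 2. Summed values had medians of 343235.2 and 395119.0. The highest sum, 3443762.5, came from cell 122, in which Mir5107, a microRNA gene that lies within Cd74 in the annotation, was listed at 3059102.8. The highest mean values belonged to Mir682 (21692.1), Rn45s, the ribosomal RNA precursor (20982.8), Mir5107 (16851.2), Actb, cytoskeletal actin (12621.5) and the small nucleolar RNA Snora68 (5839.5). The 10 genes with the largest variance over the trend included 6 short non-coding RNAs led by Mir682 and Rpph1, the RNA part of RNase P, beside Crip1, Vpreb3 and the respiratory chain genes Cox6a1 and Atp5e.

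The first question was what the sorted cells hold. Nearly all carried transcripts of the B cell receptor complex and B cell surface. Cd79b, a signalling chain of that receptor, was detected in 180 of 182 cells (98.9%, 95% interval 96.1 to 99.9), and Ms4a1, which encodes CD20, in 176 (96.7%, 93.0 to 98.8). Of the 20 genes of the germinal centre B cell list, 15 were detected in over 50% of cells. Genes of the germinal centre state were found in fewer cells than these. Mef2b, a transcription factor that drives Bcl6, was detected in 138 cells (75.8%, 68.9 to 81.9). Bcl6, the master repressor of the germinal centre program (chromosome 16, 23965052 to 23988852, mm10), was detected in 106 cells (58.2%, 50.7 to 65.5). Fas, used for the sort as a protein, was detected in 91 cells (50.0%, 42.5 to 57.5), and S1pr2, a receptor that holds B cells in the germinal centre, in 82 (45.1%, 37.7 to 52.6). At a value of 5 or more the shares were 36.3% for Bcl6 and 29.7% for S1pr2. A gene found in no more than these shares of cells was not thereby absent from the others, since transcripts can be lost from a single cell and no counts give the limit.

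Among division genes, Mki67 was detected in 152 cells (83.5%, 77.3 to 88.6) and Top2a, which untangles replicated DNA, in 153 (84.1%, 77.9 to 89.1), while 5 of 40 S phase genes and 12 of 55 G2/M phase genes were detected in over 50% of cells. Of the MHC class II genes, which serve antigen presentation, H2-Ab1 was detected in 180 cells (98.9%) and Cd74, the class II invariant chain, in 180 (98.9%, median value 2059), and the median share over the 10 genes of the list was 72.3%. Myc, which marks B cells that have just been selected for another round of division, was detected in 34 cells (18.7%, 13.3 to 25.1), with 12 in set 1 and 22 in set 2. Irf4, needed for the step to plasma cells, was detected in 24 (13.2%, 8.64 to 19.0) and Prdm1, the plasma cell regulator, in 2 (1.10%, 0.133 to 3.91). The shares of Myc and Irf4 depended on the threshold, at 9.34% and 6.59% for a value of 5 or more and at 24.2% and 23.6% above the floor. Of the 11 genes of the plasma cell list, 2 were detected in over 50% of cells.

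Markers of other cell types were mostly rare at a value of 1 or more. The 7 T cell genes in the table had a median share of 1.65%, and the exception was Lck, a kinase of T cell receptor signalling, in 99 cells (54.4%, 46.9 to 61.8), or 34.6% at a value of 5 or more. Without Lck, 2 cells had at least 2 T cell genes. Il7r was detected in 12 cells (6.59%, or 17.6% above its floor) and Cd28 in 3. Of 9 myeloid genes, Lyz2 was found in 15 cells (13 in set 1, 2 in set 2), Tyrobp in 9 and Cd14 in 8, and 8 cells had at least 2 myeloid genes. The 4 NK cell genes and the 4 stromal genes were each found together in no cell, with 3 cells holding any of either list. Of 3 erythroid genes, Hbb-bt was found in 5 cells. At a value of 5 or more the shares were 4.40% for Il7r, 0.549% for Cd28, 3.30% for Lyz2, 2.75% for Tyrobp and 1.65% for Hbb-bt. Some markers, among them Cd3e, Cd8a and Trac, are not in the table and were not analysed here.

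**Figure D1:**
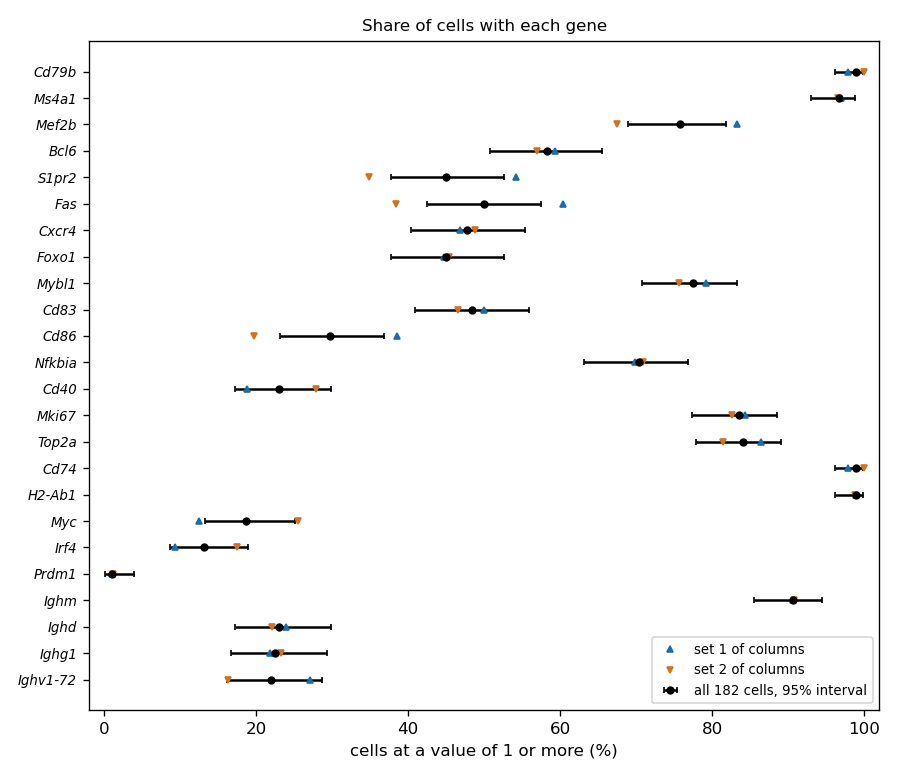
Share of cells (%) in which each gene was detected at a value of 1 or more. Black points are all 182 cells with exact 95% intervals, and triangles are the 2 sets of columns. Cd79b stands at 98.9%, Bcl6 at 58.2%, Myc at 18.7% and Prdm1 at 1.10%.

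The next question was how the cells spread between the dark zone, where germinal centre B cells divide and mutate, and the light zone, where they take up antigen and receive T cell help. The light zone and dark zone scores were opposed across cells, with a rho of -0.25 at percentile 0.03 of random pairs of lists. Among dark zone genes, the chemokine receptor Cxcr4 (chromosome 1, 128588199 to 128592293) was detected in 87 cells (47.8%, 40.4 to 55.3), Foxo1 in 82 (45.1%) and Mybl1 in 141 (77.5%). Among light zone genes, the activation marker Cd83 (chromosome 13, 43784775 to 43803132) was detected in 88 cells (48.4%, 40.9 to 55.9), the co-stimulator Cd86 in 54 (29.7%, 23.1 to 36.9), the helper receptor Cd40 in 42 (23.1%) and the NF-κB inhibitor Nfkbia in 128 (70.3%). Above the floor the shares were 69.8% for Foxo1 and 48.9% for Cd86, and at a value of 5 or more they were 29.1% for Cxcr4, 27.5% for Foxo1, 14.8% for Cd86 and 12.1% for Cd40. Mme was detected in 0 of 182 cells, which allows a share of up to 2.01%. The scores used 19 light zone and 11 dark zone genes, and Pearson's r was -0.25, or -0.23 without the 2 farthest cells. The rho was -0.16 in set 1 (percentile 6.37, not called) and -0.37 in set 2 (percentile 0.03).

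**Figure D2:**
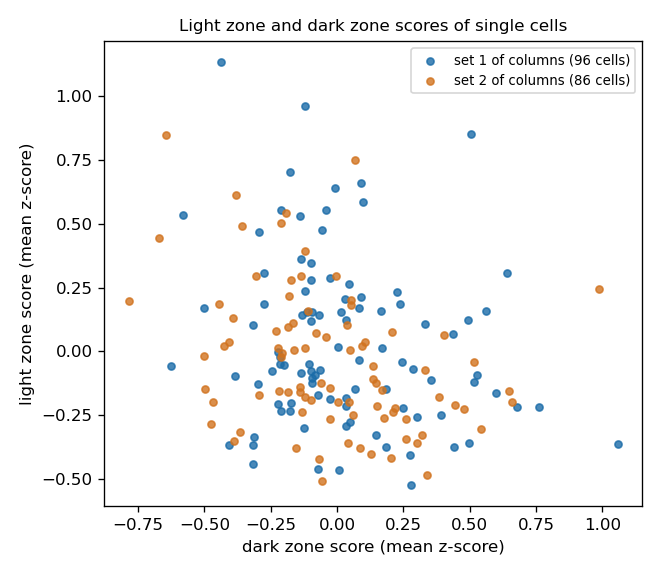
Light zone score against dark zone score of each cell, both as mean z-scores of log2 values, with colours for the 96 cells of set 1 and the 86 of set 2. Cells form a single cloud with a weak opposite trend (rho -0.25).

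Over all cells, without a term for depth or set, the zone lists did not vary together more than random lists. The mean rho between pairs of members was -0.00 for the dark zone list (percentile 22.2) and 0.03 for the light zone list (percentile 40.0), neither called. The cell cycle lists did, with 0.12 for S phase (0.13 and 0.13 within sets 1 and 2) and 0.20 for G2/M phase (0.21 and 0.16), both at percentile 100. MHC class II genes also varied together (0.12, percentile 99.9, with 0.13 and 0.13 within sets), led by H2-Aa, H2-Ab1, H2-Eb1 and Cd74. So did the lists for oxidative phosphorylation (0.19, percentile 100, with 0.19 and 0.18 within sets), heat shock (0.13, percentile 99.4), with the chaperones Hspa8 and Hsp90aa1 among its members, and Myc and ribosome biogenesis (0.08, percentile 99.6, with 0.12 and 0.07 within sets), with the nucleolar genes Ncl and Nolc1. The heat shock value was 0.07 in set 1 (percentile 95.4, not called) and 0.15 in set 2. The light zone list was called within set 1 (0.05, percentile 99.9) and not within set 2 (0.03, percentile 72.7), and also over all cells once genes above floor and set were taken into account (0.04, percentile 99.98). With the same term the glycolysis list (0.05, percentile 98.2) and the immediate early list (0.04, percentile 98.2) were called too, and the pro-survival BCL2 family list in the opposite direction (-0.12, percentile 0.61). The pro-death BCL2 family list, with 3 members, was called in set 2 only (0.15, percentile 98.6), with 0.02 in set 1 and -0.10 over all cells.

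Among the 19 gene pairs, 16 had a value and 1 was called. Cxcr4 and Cd83, the surface markers that part dark zone from light zone cells, were opposed with a rho of -0.19 (r -0.14, percentile 1.26), and both were detected in 35 cells where independence would give 42.0. The pair was opposed in set 1 (-0.33, percentile 0.08) but not in set 2 (0.06, percentile 61.7). Cxcr4 with Cd86 gave -0.08 over all cells (percentile 14.6), with -0.05 in set 1 (percentile 32.1) and -0.22 in set 2, where it passed the threshold (percentile 1.30). Over all cells Cd83 with Cd86 gave 0.08 (percentile 76.8) and Bcl6 with Irf4 -0.14 (percentile 4.10). Pairs with Prdm1 gave no value, since it was found in too few cells.

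Division was compared with the zones next. The light zone score was opposed to the G2/M phase score (rho -0.19, r -0.17, percentile 0.18) and to the S phase score (-0.13, r -0.16, percentile 1.10). The S phase list holds genes for DNA copying, such as Mcm5, Uhrf1 and Rrm2, and the G2/M phase list genes for mitosis, such as Cenpe, Nusap1 and Top2a. The dark zone score had a rho of -0.01 with G2/M phase (r 0.09, percentile 14.1, not called), with -0.07 and 0.07 within sets, and was opposed to S phase (-0.13, r -0.12, percentile 0.98). The S phase and G2/M phase scores went together (0.39, r 0.20, percentile 99.98), with 0.39 and 0.36 within sets. Light zone against G2/M phase was -0.26 in set 1 (percentile 0.81) and -0.06 in set 2 (percentile 15.6). Light zone against S phase was -0.28 in set 1 (percentile 0.38) and 0.07 in set 2 (percentile 54.9), so this relation rests on set 1. Dark zone against S phase was -0.10 in set 1 and -0.17 in set 2, called in neither (percentiles 13.3 and 3.39). Both relations with S phase also lost their call at a pseudocount of 10 and with the terms for detected genes or for genes above floor and set, and dark zone against S phase at a pseudocount of 0.1 and with scores within sets as well. In the 45 cells of the smaller Ward cluster, dark zone against S phase was positive (0.10, not called).

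The Myc and ribosome biogenesis score was compared with the zones, since Myc is known as a mark of selection in the light zone. It did not follow the light zone score (rho 0.02, r 0.07, percentile 37.6) and was opposed to the dark zone score (-0.17, percentile 0.58), with -0.09 in set 1 (percentile 17.8) and -0.26 in set 2 (percentile 0.72). Myc alone (chromosome 15, 61985391 to 61990374) had a rho of 0.05 with the light zone score, 0.12 with the rest of its list and 0.09 with G2/M phase, with percentiles of 78.0, 90.2 and 81.3. Within set 1 it followed its list (0.32, percentile 99.8) and the S phase score (0.26, percentile 99.0), and within set 2 neither (0.00 and -0.07). The smaller number of cells with Myc leaves these values imprecise.

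Scores of other lists followed the light zone score, but not all of these lists varied together among their own members. Over all cells, the mean rho between members was -0.03 for the follicular list (percentile 15.6) and 0.04 for T cell help receptors (percentile 68.5). It was 0.03 for the germinal centre B cell list (percentile 86.0), and none of these was called. The list named for receptors of T cell help had a rho of 0.37 with the light zone score (percentile 100). Within sets 1 and 2 it was 0.44 and 0.27 (percentiles 100 and 98.0). This list was scored without its zone members and held Tnfrsf13c, the BAFF receptor, and Icosl, a ligand. It is therefore not a measure of receptors for T cell help alone. Genes of follicular B cells, such as Fcer2a, which encodes CD23, and the complement receptor Cr2, had 0.38 (percentile 100), with 0.47 in set 1 and 0.21 in set 2 (percentile 95.6, not called). MHC class II genes had 0.29 (percentile 99.4), with 0.34 and 0.23 within sets (percentiles 99.7 and 91.3). The germinal centre B cell list had 0.31 (percentile 99.4), with 0.32 and 0.24 (percentiles 99.7 and 92.2). Oxidative phosphorylation genes, such as Cox4i1, Atp5b and Atp5a1, were opposed to the light zone score (-0.13, percentile 1.85), with -0.26 in set 1 and -0.04 in set 2 (percentiles 0.71 and 25.0). Glycolysis genes, such as Ldha and Pkm, were opposed to the dark zone score (-0.14, percentile 2.03), with -0.15 and -0.11 within sets, called in neither (percentiles 7.90 and 14.5), and had 0.07 with the light zone score.

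The remaining lists were not called with either zone over all cells. With the light zone score, rho was -0.02 for plasma cell, -0.02 for memory precursor, 0.07 for interferon response, 0.06 for immediate early, 0.11 for pro-survival BCL2 family, 0.08 for pro-death BCL2 family and 0.05 for heavy chain constant genes. Heat shock had -0.02 over all cells but -0.34 in set 1 (percentile 0.08) and 0.25 in set 2 (percentile 96.7). Hypermutation and class switching genes had -0.08 with the light zone score, with -0.26 in set 1 (percentile 0.67) and 0.13 in set 2 (percentile 82.4). With the dark zone score they had 0.12 over all cells, with 0.26 in set 1 (percentile 99.0) and -0.06 in set 2 (percentile 24.1).

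Genes outside the lists were ranked along the axis between the zones. At the light zone end, Nckap1l, a part of the WAVE complex in blood cells (chromosome 15, 103453794 to 103498810), had the highest rho with the light zone minus dark zone score (0.26, with 0.29 and 0.27 within sets). Irf5, an interferon regulatory factor, followed with 0.25 (0.31 and 0.14), then Calr, an endoplasmic reticulum chaperone, with 0.24 (0.20 and 0.30). Zfp36l1, which destabilises mRNA, had 0.23 (0.24 and 0.18), the lymphocyte adaptor Sash3 0.23 (0.11 and 0.33), Pdxdc1 0.23 (0.26 and 0.26) and Hivep3 0.23 (0.36 and 0.14). Others rested mostly on set 1, namely the actin regulator Vasp with 0.22 (0.37 and 0.09), Nmt2 with 0.22 (0.31 and 0.02) and Tbc1d1 with 0.21 (0.29 and 0.11). At the dark zone end stood Atp2a2, the calcium pump of the endoplasmic reticulum (chromosome 5, 122453513 to 122502225), with -0.28 (-0.29 and -0.31 within sets). Neil1, a DNA glycosylase of base excision repair found in 149 cells (81.9%), had -0.27 (-0.35 and -0.16). Sec62, a part of the protein translocation machinery, had -0.24 (-0.28 and -0.15) and Eif2ak3, the stress sensor PERK, -0.24 (-0.32 and -0.10). Akap12 had -0.23 (-0.36 and -0.19), Cdc14b -0.23 (-0.20 and -0.27), Ddx19a -0.22 (-0.25 and -0.23) and the adhesion molecule Cd2 -0.22 (-0.25 and -0.16). The centromere gene Cenpn had -0.22, with -0.33 in set 1 and too few cells for a value in set 2. Cecr2 had -0.22, which came from set 2 (-0.45), with 0.01 in set 1. These are the extremes of 5161 ranked genes, so their values are biased away from 0.

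The antibody genes gave the isotype of each cell. Most cells still expressed IgM. Of 169 cells with enough heavy chain signal, Ighm (chromosome 12, 113418558 to 113422730) was the dominant constant gene in 123 (72.8%, 65.4 to 79.3). A switched gene was dominant in 41 cells (24.3%, 18.0 to 31.4), with Ighg1 in 14 (8.28%), Ighg2b in 13 (7.69%), Ighg2c in 9 (5.33%) and Ighg3 in 5 (2.96%). Ighd was dominant in 1 cell, and 4 cells had no dominant gene. Igha was detected in 3 cells and Ighe in 9, dominant in none. The switched cells numbered 24 in set 1 and 17 in set 2. With dominance set at over 80% of the sum, the Ighm share was 62.1%.

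Ighv1-72 is the heavy chain variable gene best known from anti-NP responses of this strain (chromosome 12, 115757984 to 115758461). It was detected in 40 cells (22.0%, 16.2 to 28.7), with 26 in set 1 and 14 in set 2. In a count chosen after the values were seen, 78 cells had enough signal over the 43 variable genes in the table, and Ighv1-72 was dominant in 36 of them (46.2%, 34.8 to 57.8). The next gene, Ighv7-3, also chosen after its values were seen, was dominant in 5. Ighv1-72 was detected in 11 of the 41 switched cells (26.8%, 14.2 to 42.9) and in 26 of the 123 Ighm cells (21.1%, 14.3 to 29.4), intervals that overlap. Short and mutated variable genes map poorly and 104 cells lacked enough signal, so these shares are not those of antibody clones.

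**Figure D3:**
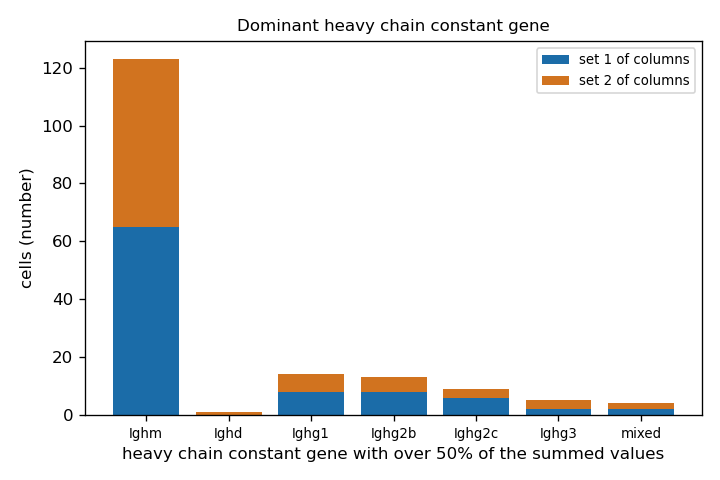
Number of cells by the heavy chain constant gene that held over 50% of the summed values, stacked by set of columns, for 169 cells. Ighm was dominant in 123 cells and a switched gene in 41.

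The last question was what separates cells when no list is given. The first principal component held 5.74% of the variance of 1000 genes and followed the oxidative phosphorylation score (rho 0.72, with 0.66 and 0.72 within sets) and the number of genes above their floor (0.65, with 0.67 and 0.64). The second held 2.65%. It had a rho of -0.70 with the G2/M phase score, -0.61 with S phase and 0.39 with the follicular list, with -0.75, -0.62 and 0.56 in set 1 and -0.58, -0.58 and 0.21 in set 2. Its rho with the number of genes above their floor was -0.39 (-0.51 and -0.21 within sets). Its leading genes were Ly6d, a surface protein of B lineage cells, and Map3k1 at one end and the histone gene Hist1h1b and the tubulin gene Tuba1b at the other. The third held 1.48% and followed the MHC class II score (0.55, with 0.55 and 0.54 within sets).

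Ward clustering gave 2 clusters with a mean silhouette of 0.316. The larger held 137 cells (75.3%, 68.4 to 81.4), 73 of set 1 and 64 of set 2. It was led by Rpph1, Lars2, a mitochondrial leucyl-tRNA synthetase, and Rpsa, and Mef2b, Mybl1 and Basp1 stood among its first 10 genes. The smaller held 45 cells (24.7%, 18.6 to 31.7), 23 of set 1 and 22 of set 2, but its share was 10.4% at a pseudocount of 0.1 and 9.38% with cells 1 to 96 alone. It was led by Ly6d, Fth1 and Ftl1, the chains of ferritin, and Vpreb3. Both clusters drew evenly on the sets, and neither had enough fixed markers among its leading genes to be named as a cell type. The smaller cluster also had more genes above their floor (median 2691 against 2335). This excess lay in the 21 cells of its Cox6a1-high part (median 3802), while the 24 cells of its Ly6d-high part had a median of 2359.5. Heavy chain genes were not used for clustering, and a switched gene was dominant in 3 of 41 cells of the smaller cluster (7.32%, 1.54 to 19.9) and in 38 of 128 of the larger (29.7%, 21.9 to 38.4).

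**Figure D4:**
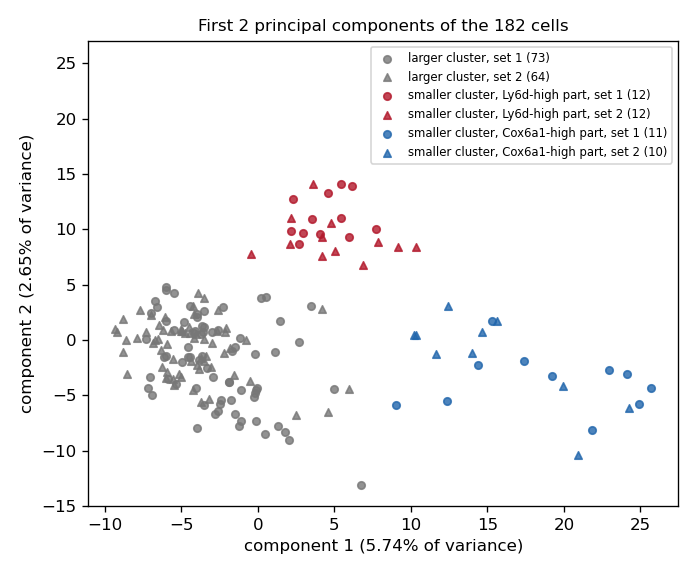
First and second principal component scores of the 182 cells (5.74% and 2.65% of variance), with colour for the larger cluster and for 2 parts of the smaller and shape for the set of columns. The 24 cells of the Ly6d-high part and the 21 of the Cox6a1-high part stand apart from the 137 cells of the larger cluster.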

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

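Alternatives chosen after seeing the data were those on set 2 alone, scores within sets, detection above the floor, the term for genes above floor and set, the filter of 3 MAD on genes above floor, each cluster alone, 3 clusters, and clustering without list members. Light zone against dark zone remained negative under all 12 alternatives and was no longer called in cells 1 to 96 (-0.16, which is also the planned filter on detected genes) and in the smaller cluster alone (-0.22). Light zone against G2/M phase was no longer called in cells 97 to 182 (-0.061) and in the smaller cluster (-0.28). Light zone against S phase was no longer called at a pseudocount of 10 (-0.094), with the term for detected genes (-0.14) or for genes above floor and set (-0.12), with the MAD filter on genes above floor (-0.093), or in the larger (-0.069) or smaller cluster (-0.22), and turned positive in cells 97 to 182 (0.065). Dark zone against S phase was no longer called at pseudocounts of 0.1 (-0.10) and 10 (-0.12), in cells 1 to 96 (-0.10) or 97 to 182 (-0.17), with the term for detected genes (-0.13) or for genes above floor and set (-0.12), or with scores within sets (-0.13), and turned positive in the smaller cluster (0.10). Cxcr4 with Cd83 turned positive in cells 97 to 182 (0.065), and dark zone against Myc and ribosome biogenesis in the smaller cluster (0.012). Fewer cells were used in the sets and clusters, and otherwise the cause was not tested. Dark zone against G2/M phase and light zone against Myc and ribosome biogenesis stayed uncalled under all 12. The first principal component held 8.01% with 500 genes, 3.97% with 2000, 5.67% without cell cycle genes, 6.49% at a pseudocount of 0.1, 5.87% with genes in 30% of cells, 6.20% in cells 1 to 96, 3.66% with the MAD filter on genes above floor and 5.72% with z-scores within sets. The smaller cluster held 10.4% of cells at a pseudocount of 0.1 and 9.38% in cells 1 to 96. The Ighm share was 62.1% with dominance at over 80%. Of 366 values for list scores along the axis, 332 kept their side of the threshold and direction, 26 lost a call, 7 gained one and 1 turned. The counts were 92 of 99 for list coherence, 72 of 77 for gene pairs and 68 of 79 for genes along the axis, while 165 of 290 shares of cells moved outside their interval. The alternatives for lambda light chains were not run, since those genes are absent from the table. Depth is unknown, so a gene listed below 1 may have been lost rather than silent.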

Other observations

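Of the tests in this part, those of the depth of the Ly6d-high cells, of B cells from outside the germinal centre, of doublets and both tests of Myc with Irf4 were chosen only after the result was seen, as were the limits for matching on depth. With 3 clusters in place of 2, a division chosen after the data were seen, the smaller cluster parted into 24 and 21 cells (12 and 12, then 11 and 10, from the 2 sets). The 24 cells were led by Ly6d, Sdc4 and Map3k1. They had low scores for division, with a difference of -0.42 from other cells for S phase and -0.48 for G2/M phase (SD 0.12 and 0.09 among these cells), and a high mean score for genes of memory precursors (0.94, with 0.99 and 0.91 within sets, SD 0.89) and for genes of follicular B cells (0.50). Because list members took part in clustering, it was repeated without any of them. This gave a cluster of 22 cells, all 22 from the same part, with differences of -0.40 for S phase and -0.46 for G2/M phase. Genes outside the lists that go with division, such as Hist1h1b and Tuba1b, stayed in the repeat. These 2 differences are therefore not independent of how the cluster of 22 cells was formed. In it Klf2, which governs B cell migration, was detected in 11 cells (50.0%, 95% interval 28.2 to 71.8) against 15 of 139 (10.8%) in the largest cluster of that run. S1pr1, the receptor for exit from lymphoid tissue, was detected in 11 (50.0%) against 10 (7.19%), and the transcription factor Hhex in 13 (59.1%) against 20 (14.4%). Foxp1, which restrains plasma cell fate, was detected in 22 of 22 (lower bound 84.6%) against 63.3%, and Ighd in 12 (54.5%) against 20.1%. Bcl6 was detected in 5 (22.7%, 7.82 to 45.4) against 68.3%, Mybl1 in 6 (27.3%) against 92.8% and Fas in 4 (18.2%) against 56.8%. Low shares of these genes are not particular to this cluster, since the third cluster of that run, of 21 cells, had Bcl6 in 6 (28.6%, 11.3 to 52.2), Mybl1 in 6 (28.6%) and Fas in 8 (38.1%, 18.1 to 61.6). Detection at 1 or more covers a similar number of genes in most cells. In cells with many genes above their floor, a gene can thus be above its floor and still below 1. Shares above the floor are not given here by cluster. Members of these lists did not all go one way. Of the 5 memory precursor genes scored, Klf2 and S1pr1 are also on the follicular list, Cd38 was detected in 7 of the 24 cells (29.2%) against 10.2% of the larger cluster, and Nt5e in 1 (4.17%) against 15.3%. Ccr6, Cd80 and Pdcd1lg2, not scored, were detected in 0 of 24, which allows up to 14.3% each. Of the follicular genes, Cd55 was detected in 8 (33.3%, 15.6 to 55.3) against 5.84%, Ccr7 in 4 (16.7%) against 4.38%, Fcer2a in 12 (50.0%) against 54.7% and Cr2 in 5 (20.8%) against 46.0%. Which genes to show here was chosen after their values were seen.

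Antibody genes were not used for clustering. Of the 24 cells, 22 had enough heavy chain signal, and Ighm was dominant in 22 of 22 (lower bound 84.6%), with 0 switched, which allows up to 15.4%, against 38 of 128 (29.7%) in the larger cluster. Ighv1-72 was detected in 1 of 24 (4.17%, 0.105 to 21.1) against 31 of 137 (22.6%, 15.9 to 30.6), intervals that overlap. These denominators include cells without enough variable gene signal. By dominance, compared after the values were seen, Ighv1-72 led in 1 of the 24, 29 of the 137 and 6 of the 21. Among cells with enough signal, it was dominant in most of the larger cluster, while nearly all such Ly6d-high cells had another dominant gene. Few Ly6d-high cells had enough signal. The 21 cells were led by Cox6a1, Shfm1, a part of the proteasome, Atp5e and Sod1, an antioxidant enzyme, and had a difference of 0.99 in the oxidative phosphorylation score and 0.46 in the G2/M phase score from other cells. Their pro-death BCL2 family score differed by 0.40 (SD 0.93), and by 0.68 in the cluster of 21 cells, 19 of them shared, from the run without list members, and their pro-survival BCL2 family score was also higher, by 0.29 and 0.32. The nuclear RNA Malat1, chosen after its values were seen, had a median value of 134.8 in them against 2116.4 in the larger cluster, and Lars2 had 1.25 against 170.2. In the 24 Ly6d-high cells Lars2 was also lower (median 10.4), while Malat1 had 1720.3. Rpph1 was detected in 25.0% of the 24 cells and 19.0% of the 21, against 69.3% of the larger cluster. In the 21 cells Hhex, Klf2 and S1pr1 were detected in 0 of 21, which allows up to 16.1% each, and Ighv1-72 in 8 of 21 (38.1%, 18.1 to 61.6), an interval that overlaps that of the larger cluster. In the matching cluster of the run without list members Hhex was detected in 2 of 21 (9.52%, up to 30.4%) and Klf2 and S1pr1 in 1 each (4.76%, up to 23.8%). The parts came back under most other settings, with 17 to 24 of the 24 cells and 17 to 21 of the 21 together when all 182 cells were used. The filter of 3 MAD on genes above floor removed 13 of the 21 cells, and the other 8 then joined all 24 Ly6d-high cells in a cluster of 36.

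Because the cells form 1 group, no biological difference between groups was tested. For the 24 Ly6d-high cells, the memory precursor difference lay at percentile 100 of lists matched on level and length. The list was high in these cells before this test, and its member Hhex took part in clustering. The test therefore cannot decide on transcript length. Across genes, the difference between these cells and the others had a rho of -0.05 with transcript length. Their 100 highest genes had a median length of 987 against 1143 over all genes. A lower depth is argued against, since these cells had no fewer genes above their floor than the larger cluster (median 2359.5 against 2335). The 16 of them at or above its median in their set differed from it by -0.42 in the G2/M phase score (percentile 0 of random lists). This low score cannot weigh on depth, since G2/M phase genes took part in forming the cluster. The test on the 16 cells replaced a pairing on depth, which could decide nothing where depths were alike. B cells from outside the germinal centre stay open, although the depletion of IgD and the gates on Fas and GL7 would remove them. Bcl6 was detected in 20.8% of the Ly6d-high cells (7.13 to 42.2), which is neither the 68.6% of the larger cluster nor under 10%. It was detected in 33.3% of the 21 other cells (14.6 to 57.0). By detection at 1 or more, low Bcl6 therefore does not set the Ly6d-high cells apart. Resting B cells carried through the sort, cells that were leaving the germinal centre, and a mix of both cannot be told apart here.

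For the 21 cells high in oxidative phosphorylation, the difference lay at percentile 100 of lists matched on level and length, whose median difference was 0.23. Because list members took part in clustering and the part was named for this list, the test cannot decide on transcript length. Without list members in clustering the difference was 0.93, which was not matched on length. The respiratory chain genes Cox6a1 and Atp5e are not on the list and stayed in that run. The value of 0.93 is therefore not independent of the clustering. The 100 highest genes of the 21 cells were short, with a median transcript length of 713 against 1143 over all genes, so length may account for parts of their profile. The 21 cells had a median of 3802 genes above floor. Over the 13 that could be paired within 10% (medians of 3294 and 3342 genes above floor), the difference from the larger cluster was 0.67. Partners came only from outside a part that was formed with list members in clustering, so this test cannot decide on depth. Doublets cannot be told apart from single cells, since genes found above their floor in 50 to 90% of the larger cluster were found in a median of 81.0% of these cells, between 64.2% in the larger cluster and 87.2% for 2 of its cells put together. An earlier form of this test on the most widely detected genes had met the value for doublets, and was replaced because genes found in nearly every cell leave little room between single cells and doublets.

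Myc and Irf4 were detected together in 10 cells where independence would give 4.96, although over all cells the pair was not called (rho 0.43, r 0.12, percentile 96.98). Different floors in the 2 sets of columns are argued against as the whole source, since the lower of the percentiles within sets was 98.3, with a rho of 0.31 in both, among genes detected in at least 5% of a set's cells. The relation remained with a term for genes above floor and set, with a partial rho of 0.32 at percentile 100. This value had been seen before the test was chosen, and genes above floor only stand in for depth. It therefore cannot decide on depth. The pair rests on few cells, and no explanation for it other than these was tested.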
